A study of Caenorhabditis elegans with 2 samples.

How the data were processed

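Chromatin immunoprecipitation followed by sequencing was carried out on whole Caenorhabditis elegans hermaphrodites carrying HIM-1 with a C-terminal GFP-FLAG tag. HIM-1 is the SMC-1 subunit of cohesin, the ring-shaped complex that holds sister chromatids together. The animals were young adults collected 47 hours after synchronization of starved larvae, per the labels. The labels' description states an antibody against GFP, while their antibody field names him-1, so the antibody is taken here from the description. The 2 libraries form 1 group and are recorded as biological replicates 1 and 2 from separate biosample entries. The labels do not say that the animals were grown as separate cultures, so differences between the replicates may in part be technical. No control library was among the samples, and control reads were not used here.

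The deposited values are peak lists on the genome builds ce10 and ce11. Per the file lists deposited with the labels, the authors called peaks against a control for each replicate and for the pooled alignments of both. The authors then thresholded the lists by the irreproducible discovery rate (IDR), which keeps peaks whose rank is repeatable, to give an optimal list. The aligner, the peak caller and their versions are not given in the sources used here. Each peak carries a signal given by the authors' peak caller, a q-value deposited by the authors as −log10, and the position of its summit. The signal scale grows with depth, so signals were used to rank peaks within a list and were not compared between lists. Read depth is unknown, because alignments and signal tracks were not used here. Intervals on shares therefore cover counting error over peaks or genes only.

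On ce11 the lists held 22720 peaks for replicate 1, 24220 for replicate 2, 18314 for the pooled replicates and 2051 in the optimal list. On ce10 the optimal list held 2046 peaks. The reference was the WBcel235 assembly, the sequence of ce11. No ce11 peak ran past the end of a chromosome, and the last peaks of chromosomes II and X ended on their last bases, 15279421 and 17718942. Coordinates are 1-based on ce11. The ce10 lists were used only in alternatives, and no coordinates were converted between builds. In the optimal list 2 intervals were repeated with a different summit and signal, and each summit was kept.

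Gene models were those of the Ensembl annotation of WBcel235, with 19973 protein-coding and 612 tRNA genes on the 5 autosomes and X. The amino acid of 607 tRNA genes and the tRNA pseudogenes came from the RefSeq annotation of the same assembly, built on WormBase release WS298. A protein-coding gene was counted as carrying a peak where a summit of the optimal list lay within 500 bp of its 5' end, and a tRNA gene where a summit lay within 250 bp of the gene. A summit counted for every gene it reached in this way, not only for the nearest. Shares of summits in a class of sequence were compared with 1000 circular shifts of the summits along each chromosome, by at least 100 kb. These permutation tests are 2-sided, and the smallest p they can give is 0.002. Shares of peaks by chromosome were tested with 2-sided exact binomial tests, and gene lists with 2-sided Fisher's exact tests against all other protein-coding genes. The Benjamini-Hochberg adjustment was applied over the 19 gene lists, the 5 sequence features and the 8 motifs. Intervals are 95% Clopper-Pearson intervals for shares and conditional intervals for odds ratios. The replicate values are shares among the 2051 peaks with the highest signal in each replicate's own list, given as mean ± SD.

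The 19 gene lists, the tests, the motifs and the alternatives were fixed before the data were examined, except where stated. In the lists, 3 symbols matched no protein-coding gene. The genes named were the protein-coding gene with the nearest 5' end for each of the 15 peaks with the highest signal, the 3 members of each list with the highest signal at the 5' end, the gene nearest each of the 3 X peaks with the highest signal, and him-1. The alternatives were the 1025 peaks with the highest signal, each replicate's own list, the ce10 lists, other windows of 100 to 1000 bp, every annotated transcript start, peaks within 1 kb counted once, and gene lists tested with X and autosomes as strata. Chance levels from summits moved by 5 to 50 kb, and results without summits within 250 bp of tRNA, rRNA, snRNA or snoRNA genes, were added after seeing the data, the latter except for the gene lists.

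The tests were tested on simulated data. In 50 sets of 2051 simulated summits with 40% planted at promoters, the mean share recovered was 39.98% and 50 sets were called, against 0 of 50 sets with no planted summits. For 20% planted at tRNA genes 50 of 50 sets were called, and 1 of 50 without. For 30% planted at 3' ends 50 of 50 were called, and 2 of 50 without. With 30% of genes planted in a list of 80 genes, 50 of 50 sets were called. In a list of 12 genes 26 of 50 were called. Over these 50 sets the other lists, with nothing planted, gave 1 call and 2 calls. The stratified test gave p under 0.05 for 6 of 100 random lists. Simulated summits and genes were drawn independently of each other, and the simulated summits were tested with fewer shifts. Real summits cluster, with 1850 left of 2051 when peaks within 1 kb were counted once. These call rates may therefore not hold for the real data. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.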

Results

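HIM-1-GFP peaks were located in young adult hermaphrodites in 2 biological replicates of 1 group. The optimal list held 2051 peaks on ce11, with a median width of 464 bp and a signal between 60.8 and 497. The comparisons ask where along the chromosomes and at which genes these peaks lay, and how far the replicates shared them. There were 424 peaks on chromosome I, 336 on II, 446 on III, 335 on IV, 287 on V and 223 on X.

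The replicates shared most of their strongest peaks. Of the 2051 peaks with the highest signal in replicate 1, 1376 (67.1%, interval 65.0 to 69.1%) had a summit within 200 bp of one in the same number of replicate 2 peaks. Circular shifts gave a mean of 0.876% and at most 1.66% (permutation p = 0.002, the smallest possible). Among optimal peaks, 85.5% of those at tRNA genes and 89.4% of those at snoRNA or snRNA genes were among the strongest peaks of both replicates. The share was 58.1% for peaks at promoters alone and 60.1% for peaks elsewhere. The median signal in the optimal list was 108 at tRNA genes, 136 at snoRNA or snRNA genes, 76.6 at promoters alone and 78.6 elsewhere, and the sharing was not compared at equal signal.

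Genes for tRNAs, which RNA polymerase III transcribes, carried HIM-1-GFP peaks far more often than chance. Of the 2051 summits, 407 (19.8%, interval 18.1 to 21.6%) lay within 250 bp of a tRNA gene. The replicates gave 19.3% ± 0.345 (SD, n = 2). Of the 612 nuclear tRNA genes, 419 (68.5%, interval 64.6 to 72.1%) carried a peak. Summits near tRNA genes lay a median of 34 bp downstream of the tRNA 5' end. The tRNA-Leu gene C14B9.t2 (III, 8109603 to 8109724), in an intron of C14B9.3, had a peak of signal 306 with its summit at 8109691. Circular shifts placed 0.29% of summits near tRNA genes, so the observed share was 68.5 times chance (permutation p = 0.002, the smallest possible).

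**Figure D1:**
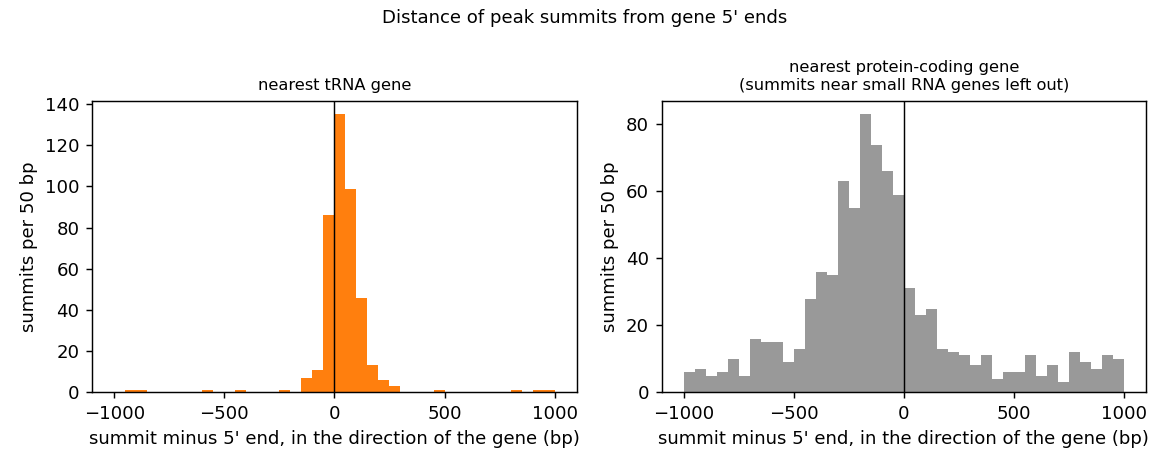
Number of summits per 50 bp (vertical axis) by distance in bp from the 5' end of the nearest tRNA gene (left) and of the nearest protein-coding gene (right, without summits near small RNA genes), with positive values downstream of the 5' end. Summits near tRNA genes gather at or close to the gene, with a median of 34 bp, and those within 500 bp of a protein-coding 5' end lie mostly upstream, with a median of -138 bp.

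The X chromosome carried fewer peaks than its length would give, and those it carried were mostly at tRNA genes. X held 223 of 2051 peaks (10.9%, interval 9.56 to 12.3%) against 17.7% of the genome length. Of the X peaks, 190 (85.2%) lay at a tRNA gene, against 217 of 1828 (11.9%) on the autosomes. Only 22 of 2731 X protein-coding genes (0.806%) carried a peak at the 5' end, against 870 of 17242 autosomal genes (5.05%). The replicates gave 0.824% ± 0.129 for X and 4.77% ± 0.320 for the autosomes (SD, n = 2). For tRNA genes the order was the opposite, with 203 of 276 (73.6%) on X and 216 of 336 (64.3%) on the autosomes. Single autosomes ran from 53.0% on I to 73.4% on III. X and autosomal tRNA genes were not compared at equal numbers of identical copies in the genome. The strongest X peak (signal 334, summit at 3036109) lay in intergenic sequence upstream of M02F4.2, within 250 bp of the tRNA genes M02F4.t1 for Gly and M02F4.t2 for Glu. The next was in an intron of egl-17, which encodes a fibroblast growth factor, at the tRNA-Asp gene F38G1.t2 (489868 to 489939, signal 236). The 41 bases around its summit, X 489857 to 489897, read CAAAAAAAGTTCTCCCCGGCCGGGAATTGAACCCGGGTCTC. The peak ranked after it on X (summit at 9743710, signal 236) lay in an intron of him-4, beside the tRNA-Ala genes F15G9.t1 and F15G9.t2; the nearest protein-coding 5' end was that of F15G9.5.

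The X share was below the share of length (exact binomial p = 1.28e-17) and below the 13.7% of protein-coding genes on X (exact binomial p = 0.000167). The odds ratio of X against autosomes was 0.153 (interval 0.0951 to 0.233, Fisher's exact p = 3.52e-32) for promoters and 1.54 (interval 1.08 to 2.23, Fisher's exact p = 0.0146) for tRNA genes. Among the 1025 peaks with the highest signal the X share was 16.2% (interval 13.99 to 18.6%), which no longer differed from the share of length (exact binomial p = 0.235) and lay above, not below, the 13.7% of genes. Without summits near tRNA, rRNA, snRNA or snoRNA genes, a setting chosen after seeing the data, X held 31 of 1482 peaks (2.09%), or 1.75 per Mb against 17.6 per Mb on the autosomes. In that setting 3 of 2731 X promoters and 792 of 17242 autosomal ones carried a peak, an odds ratio of 0.0228 (interval 0.0047 to 0.0671).

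**Figure D2:**
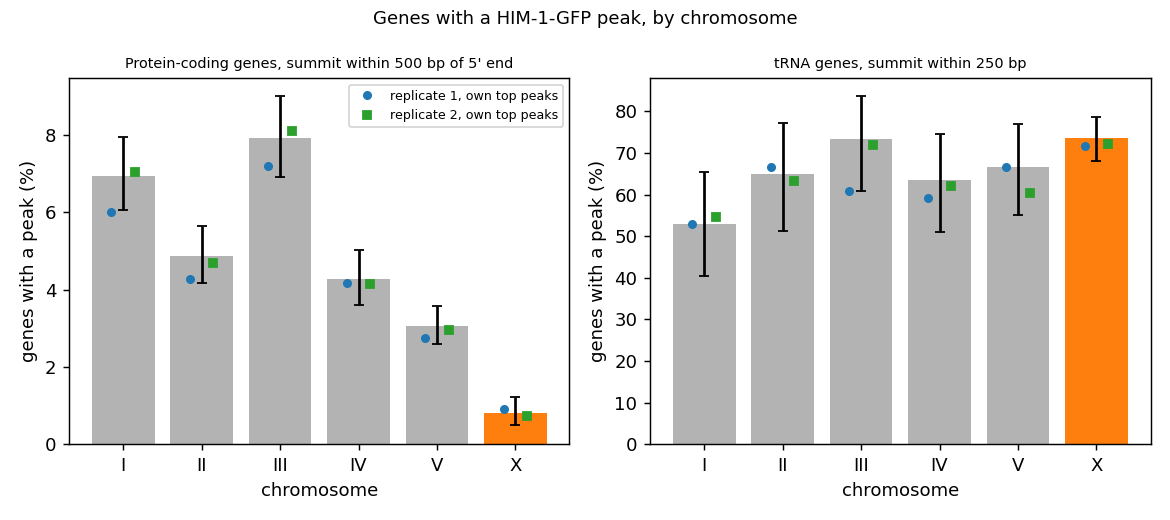
Percent of protein-coding genes (left) and tRNA genes (right) with a peak on each chromosome; bars are the optimal list, error bars 95% Clopper-Pearson intervals, and points the strongest peaks of each replicate. X (orange) has the lowest bar for protein-coding genes at 0.806% and is highest for tRNA genes at 73.6%, beside III at 73.4%.

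Both ends of protein-coding genes held more summits than chance. Within 500 bp of a 5' end lay 758 summits (37.0%, interval 34.9 to 39.1%), and the replicates gave 35.9% ± 1.83 (SD, n = 2). These summits were mostly upstream: away from small RNA genes, 78.0% of 656 lay before the 5' end, at a median of -138 bp. Within 500 bp of a 3' end and away from 5' ends lay 724 summits (35.3%, interval 33.2 to 37.4%), with 35.2% ± 2.24 in the replicates (SD, n = 2). At closely spaced convergent genes, whose 3' ends face each other, lay 198 summits (9.65%). This class takes in the sequence between the 3' ends and 500 bp into each gene, away from 5' ends. Circular shifts gave 18.7% for promoters, 12.03% for 3' ends and 2.14% for convergent 3' ends, and each of these shares was above all 1000 shifts (permutation p = 0.002, the smallest possible).

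Coding exons held fewer summits than chance and sequence between genes held more. Summits fell in coding exons in 7.41% of cases against 25.1% by chance, and in introns in 23.0% against 34.5%. Intergenic sequence held 59.3% against 35.6%, 3' UTRs 7.80% against 3.41% and 5' UTRs 2.49% against 1.42%. All 5 features passed the permutation test (adjusted p = 0.002). Among the 1025 strongest peaks the 5' UTR share was 0.878% and did not differ from chance (adjusted permutation p = 0.202).

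Oocyte and eggshell, ribosomal protein, germ granule and DNA replication genes carried optimal peaks within 500 bp of the 5' end more often than other genes. Of the 19 lists, 7 were above the other protein-coding genes and 1 was below. Of 17 oocyte and eggshell genes 8 carried a peak (47.1%, interval 23.0 to 72.2%). They included cpg-1, a chondroitin proteoglycan of the eggshell (signal 232), egg-1, a sperm-egg fusion receptor (signal 140), and rme-2, the yolk receptor (signal 113). Of 80 cytosolic ribosomal protein genes 28 did (35.0%, interval 24.7 to 46.5%), with the strongest signals at rpl-35 (297), rpl-3 (274) and rpl-20 (198). This count depended on the window, with 7 genes (adjusted Fisher's exact p = 0.0198) at 250 bp and 43 at 1000 bp, and was 14 among the 1025 strongest peaks. Of 30 germ granule and germline RNA genes 9 did (interval 14.7 to 49.4%), among them pie-1 (154), mex-1 (95.8) and pos-1 (91.3), which encode zinc finger proteins of the early germ line. Within 250 bp 4 of the 30 did (adjusted Fisher's exact p = 0.0243), and among the 1025 strongest peaks 5 did (0.00114). Of 34 DNA replication and cell cycle genes 11 did (32.4%), including pcn-1, the sliding clamp of replication (141), and the helicase genes mcm-3 (85.9) and mcm-6 (85.5).

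Cohesin's own genes were among the lists with peaks. Of 12 cohesin genes 4 carried one (33.3%, interval 9.92 to 65.1%), including the meiotic kleisin genes coh-3 (85.9) and coh-4 (62.8) and the regulator gene evl-14 (61.6). The coh-4 summit lay nearer the 5' end of the neighbouring gene pid-5 than that of coh-4. Of 31 synaptonemal complex and meiotic recombination genes 5 did (16.1%), including syp-4 (248), zhp-3 (101.4) and him-14 (64.6). The syp-4 summit also lay within 250 bp of the snRNA gene H27M09.6. Of 59 heat shock and chaperone genes 7 did (11.9%), including dnj-9 (126.1), cct-8 (101.4) and cct-1 (86.8). Of 17 condensin and dosage compensation genes 2 did (11.8%), hcp-6 (87.2) and smc-4 (82.1). The tagged gene him-1 (I, 4951571 to 4957667, minus strand) had no optimal summit within 500 bp of its 5' end, and the nearest lay upstream at -6871 bp, with its summit at 4964538 (signal 67.5).

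Chemoreceptor genes, expressed mainly in sensory neurons, carried few peaks: 10 of 1309 (0.764%, interval 0.367 to 1.40%), of which srh-269 (144), srz-97 (124) and sri-5 (121) had the highest signals. The srh-269 summit lay within 250 bp of the tRNA-Gln gene T03E6.t1 and the srz-97 summit within 250 bp of the snRNA gene F08H9.11, and without summits near small RNA genes 7 of the 1309 carried a peak. Markers of somatic tissues were at 0 of 28 for intestine, 1 of 36 for muscle (mlc-3, signal 81.6) and 1 of 37 for neurons (tdc-1, 72.9). Major sperm protein genes were at 0 of 31 and Hox and homeobox genes at 1 of 89 (ceh-43, 111). Of 178 cuticle collagen genes 7 carried a peak (3.93%), and the highest signals were at col-85 (150), col-54 (141) and col-38 (70.2). The summits at ceh-43, col-85 and col-54 lay in introns of these genes, at tRNA genes. Translation factor genes were at 4 of 33 (eif-3.C 124, eef-1A.1 93.4 and eef-2 66.7), proteasome genes at 2 of 31 (rpn-2 81.4 and rpn-11 71.9) and histone genes at 2 of 72 (his-67 and his-68, which share 1 peak of signal 133). F-box and MATH/BTB genes were at 10 of 395, led by fbxa-140 (95.8), fbxc-45 (85.8) and bath-44 (82.9). In the own lists of replicates 1 and 2, peaks lay at 4 and 4 histone genes, 5 and 3 proteasome genes, 4 and 5 cuticle collagen genes and 2 and 0 neuron markers.

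Of all protein-coding genes 4.47% carried a peak. Because a summit counted for every gene within 500 bp, the counts of a list are not independent of neighbouring genes. The summits named for mcm-3, rpl-20, cct-1, cct-8, eef-1A.1 and col-38, like that of coh-4, lay nearer the 5' end of a neighbour. For these 6 genes the neighbours were, in order, C25D7.15, Y17G9B.5, mig-5, Y55F3AR.2, rfc-4 and rpl-5. Against the genes outside each list, adjusted p by Fisher's exact test was 6.28e-17 for ribosomal proteins, 9.34e-07 for DNA replication, 1.24e-06 for oocyte and eggshell, 1.58e-05 for germ granules, 0.00464 for cohesin, 0.0308 for meiotic recombination and 0.0372 for heat shock. It was 1.21e-14 for chemoreceptors. The other 11 lists did not pass, with adjusted p from 0.121 to 1. Replicate 1 alone had peaks at 20 ribosomal protein and 5 DNA replication genes and replicate 2 at 32 and 9. The call for meiotic recombination ended without summits near small RNA genes (4 of 31, adjusted exact p = 0.0793), with replicate 2's own list (4 of 31, adjusted p = 0.0974) and with windows of 250 bp (0.113) and 1000 bp (0.0829), and that for heat shock ended with a window of 250 bp (2 of 59, adjusted p = 0.796). Among the 1025 strongest peaks the cohesin (1 gene, adjusted p = 0.393), DNA replication (3 genes, 0.102), meiotic recombination (2 genes, 0.276) and heat shock (3 genes, 0.276) calls ended by the same exact test.

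**Figure D3:**
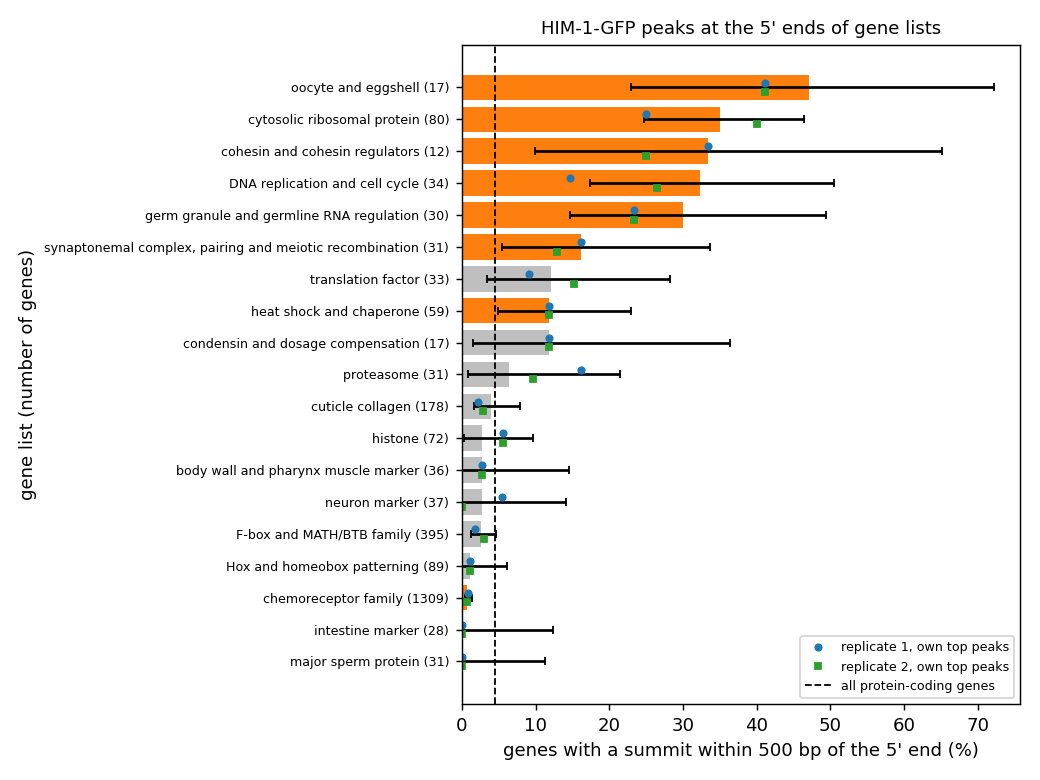
Percent of the genes in each list with a summit within 500 bp of the 5' end; bars are the optimal list with 95% Clopper-Pearson intervals, orange where the adjusted p is under 0.05, points the strongest peaks of each replicate, and the dashed line all protein-coding genes (4.47%). Oocyte and eggshell genes are highest at 47.1%, and chemoreceptors are below the line at 0.764%.

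Autosomal peaks gathered towards chromosome centres, where many widely expressed genes lie. The middle 33.3% of the autosomes' length held 757 of 1828 peaks (41.4%, interval 39.1 to 43.7%) (exact binomial p = 6.59e-13 against 33.3%). The comparison is with length only. The share of genes in that part was not computed, and a link to gene density or expression was not tested. Chromosome III had the most peaks per Mb, at 32.4, and V the fewest of the autosomes, at 13.7.

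The sequence within 100 bp of the summits was richer in G and C than chance, with a median of 38.3% against 35.2% (permutation p = 0.002, the smallest possible). Without summits near small RNA genes, a setting added after seeing the data, the median was 36.3% against 35.3% (permutation p = 0.00599). The GC box CCGCCC or CCCGCC occurred at 11.99% of summits against 5.82% by chance, and GAGAGA at 14.8% against 10.2%. TCGCGCAGGG, the start of a motif of dosage compensation sites on X, occurred at 4 summits (0.195%) against 0.00375%. These had adjusted permutation p = 0.0032 and were also above chance in each replicate's own list. The TCGCGCAGGG share was 0.0975% in each replicate's own list, and 0 of the 1025 strongest peaks had it. TGANTCA (4.10% against 5.61%), TATAAA (18.04% against 20.9%) and TTTTTTTT (20.9% against 23.2%) were below chance, with adjusted permutation p of 0.0032, 0.0032 and 0.0373. None of these 3 passed without summits near small RNA genes or in replicate 1's own list, and TGANTCA and TATAAA did not pass in replicate 2's either. TGANTCA also did not pass among the 1025 strongest peaks (adjusted permutation p = 0.0735), nor TTTTTTTT against summits moved by 5 to 50 kb (0.152). CACGTG (3.75%) and GATAAG (6.78%) did not differ from chance (adjusted permutation p = 0.490 for each).

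None of the 15 peaks with the highest signal lay within 500 bp of a protein-coding 5' end. The strongest (signal 497, III 12537218 to 12537817) lay in intergenic sequence, with its summit at 12537439 and 1225 bp past the 3' end of aakg-1; the nearest 5' end was that of sql-1, 37882 bp away. The same interval held the summit ranked 10, at 12537646 (signal 314). The peak ranked 2 (I 13792161 to 13792713, signal 496) had its summit 169 bp past the 3' end of ndx-4, and those ranked 4 and 13 (407 and 298) lay past the 3' ends of ubc-14 and vps-28. The peak ranked 3 (V 8500452 to 8500682, signal 436) was in an intron of pxn-1, within 250 bp of the snoRNA gene ZK994.7. The summits of the peaks ranked 5 (355) and 8 (328) lay in the 3' UTRs of wsp-1 and cpsf-1, the latter with xpc-1 as the nearest 5' end. The peaks ranked 6 (346, nearest 5' end ZK1248.17) and 11 (307, sepa-1) lay beside sls-2.1 and sls-2.9, genes of the SL2 RNA that is spliced onto downstream genes of operons; that ranked 11 also lay within 250 bp of the tRNA-Lys gene M01E5.t1. The peak ranked 9 (317) lay 28 bp past the 3' end of atf-7, with cpg-1 as the nearest 5' end, and that ranked 14 (298) was nearest the 5' end of Y48G1C.13. The peak ranked 15 (297, nearest 5' end srsx-22) lay in an intron of C08D8.1 beside the snoRNA gene C08D8.3. Of the 58 peaks named by rule, 52 were among the strongest peaks of replicate 1 and 54 among those of replicate 2.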

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

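The relaxed list of the pooled replicates was made as input to the IDR step and holds background as well as peaks, with −log10 q-values down to 0.0179. The tests of this list were chosen after the main values had been seen. Its 16090 entries that lay over 200 bp from any optimal summit enter no comparison above, and they lay near genes more often than chance. At tRNA genes lay 1.22% of them against 0.265% in 200 circular shifts, and at promoters 27.5% against 18.9% (permutation p = 0.00995 for each, the smallest these shifts can give). Of the 612 tRNA genes, 20.1% had such an entry and no optimal peak. Of the X protein-coding genes 7.43% had such an entry at the 5' end, against 24.0% of the autosomal ones.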

How the results depend on the processing

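Settings named here as added were chosen after seeing the data. The shares at promoters (23.0% to 50.1%), 3' ends (26.5% to 42.04%) and tRNA genes (18.7% to 29.6%), the middle of the autosomes (39.5% to 42.8%), the replicate overlap (57.9% to 70.7%) and the GC content kept their direction and their side of the threshold under every alternative run. The X share stayed below the share of length under each, from 2.09% to 16.2%, but did not pass among the 1025 strongest peaks (16.2%), where tRNA genes held 29.6% of summits. Gene lists past the threshold numbered 8, and 4 among the 1025 strongest peaks, which leave fewer genes with a peak. Translation factors (5 of 33) passed in replicate 2's own list, and proteasome (5 of 31, above) and F-box genes (7 of 395, below) in replicate 1's. Motifs past the threshold numbered 6, between 3 and 4 in the replicates' own lists, and 3 without summits near small RNA genes, an added setting; the cause was not tested. Among results past the threshold in the main setting, the direction turned for 5' UTRs (0.878%) and TCGCGCAGGG (0% of summits) among the 1025 strongest peaks, and for TTTTTTTT (24.0%) without summits near small RNA genes, none of them past the threshold there; the cause was not tested. It also turned for some lists that did not pass, such as histone genes, at 2 of 72 in the optimal list and 4 of 72 in each replicate's own. Of the recomputed values with a test, single lists, features and motifs included, 222 kept their direction and their side of the threshold and 34 did not keep both. No paired analysis was possible because the samples form 1 group. Depth is unknown, so the peaks missing from one replicate's list cannot be tied to it, and in simulated data a list of 12 genes with 30% of them planted was called in 26 of 50 sets.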

Other observations

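Other small RNA genes also carried HIM-1-GFP peaks; all tests in this part except those of tRNA genes against the shifts were chosen after the main values had been seen. Of 18 genes of the SL2 RNA 14 carried a peak (77.8%, interval 52.4 to 93.6%), and of 12 of the SL1 RNA, which lie in a tandem repeat with 5S rRNA genes, 0 did (upper bound 26.5%). Whether peaks can be called in this repeat was not tested, so few peaks at SL1 or 5S rRNA genes need not mean that HIM-1-GFP is absent there. Of 346 snoRNA genes 87 carried a peak (25.1%) and of 129 snRNA genes 51 (39.5%). Summits near snoRNA genes made up 4.73% of all against 0.227% by chance, near snRNA genes 3.22% against 0.0773% and near microRNA genes 0.683% against 0.135% (adjusted permutation p = 0.00266 for each over 4 classes). Near rRNA genes lay 1 summit (adjusted permutation p = 0.553). Of 209 tRNA pseudogenes 13 carried a peak (6.22%), against 68.5% of tRNA genes (Fisher's exact p = 2.39e-61). Among amino acids the share of tRNA genes with a peak ran from 50% for His and Phe to 84.6% for Leu, leaving out the single gene for Sec, and none differed from the rest after adjustment (lowest adjusted Fisher's exact p = 0.40).

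Of the 22 X protein-coding genes with a peak at the 5' end, 3 kept one without summits near small RNA genes: epn-1, T13C5.6 and ZK816.3. All 4 summits with TCGCGCAGGG lay on X, at 4209296, 6296623, 2997034 and 11094061, with signals between 63.3 and 69.9. They lay between -3319 and 4125 bp from the nearest protein-coding 5' ends, those of F20B6.9, cest-16, Y41G9A.17 and W02H3.3. These genes and sites were picked after their values were seen.

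Few X promoters carried a peak. A lower signal over the whole of X was predicted to make peaks rarer at X tRNA genes too. Their odds ratio against autosomes was 1.54 (interval 1.08 to 2.23), wholly above that of promoters. This cannot exclude a drop, because a peak is a call above a cutoff. The lowest optimal signal was 60.8, and the median was 76.6 at promoters alone and 108 at tRNA genes. Signals at X and autosomal tRNA genes were not compared, nor were their shares at equal numbers of identical copies. In the relaxed pooled list, X held 1205 of the 16263 entries whose summit was not an optimal one. This is 7.41%, against 17.7% of the length, so a lower signal over X stays open. A lack on X of the fixed gene lists that carry peaks is argued against, since among genes in none of the lists the odds ratio was 0.153 (interval 0.0937 to 0.235). Most genes with a peak were outside the lists, 21 on X and 759 on the autosomes. Whether X lacks other kinds of genes that carry peaks was therefore not tested. Another candidate explanation that stays open is lower transcription of X genes in the germ line, which was not tested, since the design has 1 group.

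At tRNA genes, reads shared between identical copies may raise signal in part. Of 140 tRNA genes whose sequence occurs once, 47.9% carried a peak (interval 39.3 to 56.5%) against 1.03% by chance. Of 472 with copies 74.6% did (Fisher's exact p = 7.33e-09 for the difference). Peaks were thus also found at genes without an identical copy. Reads shared with similar genes, or a summit of a neighbouring tRNA gene, were not separated out, so the part played by shared reads stays open. Of 57 families of identical genes 64.9% (interval 51.1 to 77.1%, just above a bound of 50% that was chosen once the single-copy result was known) held both copies with and copies without a peak, fewer than the 74.5% of permutations (permutation p = 0.044), so some sharing stays open. Promoters of neighbouring genes are argued against, as 67.1% of tRNA genes over 1 kb from a protein-coding 5' end carried a peak (interval 62.4 to 71.5%) against 71.7% of nearer ones. Nonspecific recovery of strongly transcribed chromatin was not tested, and neither was a biological explanation.

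Of the optimal summits, 651 (31.7%) lay over 1 kb from any protein-coding 5' end and over 250 bp from tRNA, snoRNA and snRNA genes, and 19.97% of these were in 3' UTRs. Shifted summits that met the same distances gave 3.21% (permutation p = 0.002, the smallest possible). Repeated sequence is argued against. Of the 651, 1.84% (interval 0.956 to 3.20%) had over 50% of their 36-base words repeated elsewhere, against 7.44% by chance. The authors' handling of repeated reads is unknown and may have lowered this share of the 651 summits. The B box GTTCGANNC of polymerase III genes lay within 100 bp of 43 of them (6.61%, interval 4.82 to 8.79%) against 1.55% by chance (1.496% for shifted summits that met the same distances; permutation p = 0.002, the smallest possible), and 9 of the 43 were near tRNA pseudogenes. Unannotated polymerase III genes may therefore account for part of these peaks, and 608 had no such box. The box lay at 65.8% of summits at tRNA genes, so its absence does not exclude a polymerase III gene. No biological explanation was tested.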
